A study of Mus musculus with 9 samples.

How the data were processed

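Messenger RNA from 9 mouse T helper cell cultures was sequenced, with 3 libraries each of Th1, Th17 and Th17-derived Th1 cells. Per the labels' protocols, naive T cells were activated for 3 days with anti-CD3 (5 ug/mL) and anti-CD28 (1 ug/mL, where the series text has mg/mL for both), kept in IL-2 (100 U/mL) from day 5, and activated again on day 7 with both antibodies at 0.05 ug/mL. The Th1 condition held IL-12 at 10 ng/mL, and the Th17 condition TGF-beta at 1, IL-6 at 20 and IL-1beta at 10 ng/mL. RNA was taken on day 10. Groups and replicate numbers come from the sample titles.

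The authors deposited FPKM values, which are fragments scaled by transcript length and by the mapped fragments of the library, for 22017 gene symbols in 9 libraries. Per the submitters' processing notes, the mm10 genome build, HISAT2 and DESeq2 were used. Their versions and roles, the gene annotation and the treatment of reads that map to several places are not given in the sources used here. Of the symbols, 21962 were found in the reference annotation (GRCm38, from which gene positions were taken), 15 had been changed to dates, and 5692 genes were at 0 in all 9 libraries. FPKM values hold no read counts, and low values did not fall on shared steps (the commonest ratio between libraries covered 0.780% to 1.15% of low genes at a tolerance of 0.01 log2 units), so depth could not be recovered and is unknown. FPKM depends on the composition of each library: a few very abundant transcripts lower the values of all others, so scaling was varied.

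Values were tested as log2(FPKM + 1), where differences of low genes are understated. Genes with at least 1 FPKM in at least 3 libraries were kept (10538). limma (version 3.58.1, R 4.3.3) was fitted with a mean-variance trend to all 9 libraries, so that the 3 groups shared an estimate of the spread with 6 residual degrees of freedom before moderation, and two-sided p-values of each contrast were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 of 30 lists with at least 5 tested members, and again with the correlation estimated for each list. With an estimated correlation camera called 0 lists in each comparison, while 2 in Th17-derived Th1 against Th1, 6 against Th17 and 3 in Th1 against Th17 had an unadjusted p below 0.05. The limma test fry, which asks whether the genes of a list move 1 way without comparing them to other genes, called 8, 12 and 15 lists in the same order. Tables were drawn and joined with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

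Groups, contrasts, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered the Th1, Th17, Th2, T follicular helper and regulatory T cell programs, progenitor and memory-like cells, inhibitory receptors and exhaustion, cytotoxic effectors, interferon-stimulated, TGF-beta response and T cell receptor-induced genes, chemokine receptors, cytokines, cell cycle, metabolism, the unfolded protein response, T cell identity, and markers of CD8, gamma-delta, NK, B, dendritic, macrophage, neutrophil, mast and erythroid cells. Named genes were 28 key genes, of which 3 were too low to test, the 8 largest differences per direction and comparison with no overlap between groups, a mean of at least 5 FPKM and no predicted, clone or antigen receptor segment name, up to 4 called members per direction of each list, and the 8 largest in each direction against both other groups. Some genes under this rule are not reported here.

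The position of Th17-derived Th1 cells was the median over genes of their distance from Th17 in units of the distance between Th17 and Th1. The fit was tested on simulated data with 200 changed genes. At 1.5-, 2- and 4-fold it recovered 46.3%, 80.6% and 100% in Th17-derived Th1 against Th1 (10396 genes), 55.2%, 82.1% and 100% against Th17 (10394 genes) and 32.8%, 82.1% and 100% in Th1 against Th17 (10381 genes), with 5.03%, 2.47% and 4.67% false calls. Low genes were not among those changed, and noise was drawn independently for each gene with the fit's own variances. These rates therefore do not cover low genes or structure shared between libraries. Alternatives were a replicate block, pseudocounts of 0.1 and 5, other filters, 3 other scalings (equal sums, median ratio and quantile), fits of 2 groups only, array weights, robust moderation, stricter thresholds and the omission of each library. Fits without replicate 3 and with the mean log2(FPKM + 1) of Cd8a and Cd8b1 as a covariate were added after the data were seen. Antigen receptor constant genes, Xist and Malat1 are not listed in the table and were not analysed here.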

Results

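RNA sequencing measured messenger RNA in 9 libraries of mouse T helper cells, 3 in each of 3 groups. Naive T cells from C57BL/6 spleens were activated for 3 days through CD3 and CD28 under conditions that drive a Th1 or a Th17 fate. Th1 cells are helper cells that secrete interferon-gamma and were induced with IL-12, and Th17 cells secrete IL-17 and were induced with TGF-beta, IL-6 and IL-1beta. The Th17 medium also held antibodies against interferon-gamma, IL-12 and IL-4. Cells were activated again on day 7 and RNA was taken on day 10. At that second activation the Th1 and Th17 groups kept their conditions, whereas the group called Th17-derived Th1 passed from the Th17 to the Th1 condition. The title of the series names a likeness of such converted cells to progenitor exhausted T cells, a pool of chronically stimulated T cells that keeps the transcription factor TCF-1.

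Summed over genes, a library held 382581 to 405985 FPKM, and 13374 to 14063 genes had a value above 0. The read depth behind these values is unknown, so no counting interval is given. Libraries of 1 group correlated at 0.964 to 0.993 across genes, which are not independent replicates, and no pair of columns was identical. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be partly technical. Over the 3 groups, Gm47283, a gene described below, was at 0 FPKM in replicate 1, 19.2 to 23.0 in replicate 2 and 67.4 to 120.5 in replicate 3. These values argue against replicates that only repeat 1 culture, but what separates the numbers is unknown. Cd8a, a chain of the CD8 co-receptor of cytotoxic T cells (chromosome 6, 71373427 to 71379173), was at 104 to 141 FPKM in replicate 3 of each group and at 15.3 to 54.9 FPKM in the other 6 libraries. Cd8b1, the other chain, was at 48.1 to 62.9 and at 4.54 to 24.1 FPKM. Cd4, the co-receptor gene of helper T cells, was at 52.9 to 96.9 FPKM in replicate 3, below Cd8a in each group. In the other 6 libraries Cd4 was at 81.1 to 123.6 FPKM, above Cd8a in each. The first principal component held 60.2% of the variance between libraries, and the next components held 15.3% and 12.9%.

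**Figure D1:**
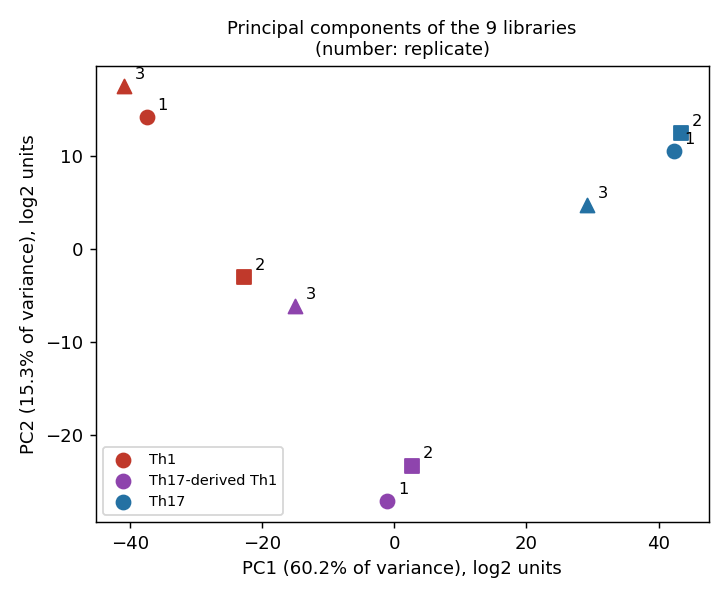
Principal components of log2(FPKM + 1) over the 10538 tested genes, with the share of variance on each axis (60.2% and 15.3%). Each point is 1 library, colored by group and shaped by replicate number.

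The first comparison set Th1 against Th17 cells and asked which genes separate the 2 groups. Each kept its own condition at the second activation, so fate cannot be told apart from the cytokines and antibodies of the medium. Ifng, which encodes interferon-gamma (chromosome 10, 118441046 to 118445892), averaged 1385 ± 548 FPKM in Th1 and 24.9 ± 14.0 FPKM in Th17 cells (SD, n = 3 in each group, here and below), a 55.8-fold difference on the log2(FPKM + 1) scale. Tbx21, which encodes the Th1 lineage factor T-bet (chromosome 11, 97098071 to 97115331), averaged 85.9 ± 16.1 against 8.51 ± 3.33 FPKM, 9.38-fold. Il17f, a Th17 cytokine gene, averaged 0.0129 ± 0.0223 against 7.99 ± 0.678 FPKM, a log2 difference of -3.15, and Il17a was listed at 0 in all 3 Th1 libraries and averaged 4.46 ± 1.60 FPKM in Th17 cells. Tcf7, which encodes TCF-1 (chromosome 11, 52252371 to 52283014), averaged 52.0 ± 26.5 against 371 ± 93.3 FPKM, a log2 difference of -2.91. Their limma adjusted p-values (Benjamini-Hochberg) ran from 4.03e-06 for Il17f to 0.000457 for Tcf7.

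By size of difference, Csf1, a growth factor of macrophages, led the genes higher in Th1 at 309.6 ± 170.3 against 1.18 ± 0.600 FPKM, 126-fold. Next to it and to Ifng stood the granzyme genes Gzmd (59.6-fold) and Gzme (44.2-fold), the chemokine gene Ccl5 (47.3-fold), P2rx3 (31.5-fold), Serpine2 (24.5-fold) and Il1rl1 (23.9-fold). Itgae, the CD103 integrin chain induced by TGF-beta (chromosome 11, 73090583 to 73147446), led the genes lower in Th1 at 0.856 ± 0.285 against 106 ± 3.86 FPKM, a log2 difference of -5.85. It was followed by Ncmap (-4.39), Spsb1 (-4.02), Rflnb (-3.94), Apol9b (-3.72), the IL-6 receptor gene Il6ra (-3.71), Cdh1 (-3.69) and the gut homing receptor gene Gpr15 (-3.68). The adjusted p-values of these 16 genes ran from 2.46e-06 (Itgae) to 0.000345 (Gzmd). Gzmd, Gzme and Gzmg are close paralogs, as are Ifit3, Ly6g, Ly6c2, Apol9b and the Gbp genes with their neighbors, and how reads shared between such copies were assigned is not given, so their values are uncertain.

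Of 23 measured members of the Th1 program, 16 were higher, 2 were lower and 5 did not pass (16 and 2 adjusted over the list alone, median log2 difference 1.89, camera adjusted p = 5.66e-10, adjusted p = 0.38 with an estimated correlation). Among them, Ccl5 was 47.3-fold and Furin 15.9-fold higher, while Eomes, a T-box factor, was at 11.5 ± 5.44 against 28.8 ± 13.6 FPKM. Of 24 cytotoxic effector genes, 16 were higher, 1 was lower and 7 did not pass (16 and 1 adjusted over the list alone, median log2 difference 1.36, camera adjusted p = 4.74e-08, adjusted p = 0.452 with an estimated correlation). Prf1, which encodes the pore-forming perforin, averaged 218 ± 56.1 against 17.4 ± 13.0 FPKM. Gzmb, the main granzyme, was at 3569 ± 1086 against 1483 ± 1025 FPKM, 2.69-fold (adjusted p = 0.0224). The libraries with the most Cd8a moved with this group: the median cytotoxic gene was higher in replicate 3 than in replicates 1 and 2 by 0.54 log2 units in Th1, 0.98 in Th17-derived Th1 and 1.04 in Th17 cells, and the median Th1 program gene by 0.23, 0.39 and 0.60. NK cell markers (0.595, 0.463 and 0.447), dendritic cell markers (0.323, 0.456 and 0.577), inhibitory receptor and exhaustion genes (0.308, 0.456 and 0.301) and T cell receptor-induced genes (0.239, 0.314 and 0.301) also had medians above 0 in replicate 3 of each group. So did interferon-stimulated genes (0.114, 0.183 and 0.687), cholesterol synthesis genes (0.127, 0.258 and 0.521) and B cell markers (0.143, 0.216 and 0.223). Medians below 0 in replicate 3 of each group were those of T follicular helper (-0.13, -0.252 and -0.367), Th2 (-0.189, -0.385 and -0.058) and regulatory T cell genes (-0.063, -0.133 and -0.114). The remaining lists differed in sign between groups, with progenitor and memory-like genes at 0.126, 0.131 and -0.531. Of 16 Th17 program genes, 6 were higher, 8 were lower and 2 did not pass (6 and 8 adjusted over the list alone, median log2 difference -0.73, camera adjusted p = 0.981, adjusted p = 0.989 with an estimated correlation). Besides Il17a and Il17f, the aryl hydrocarbon receptor gene Ahr was lower in Th1 (log2 difference -2.99), whereas Csf2 (5.98-fold), Cxcr6 (2.56-fold), Ltb4r1 (2.70-fold) and Batf (2.56-fold) were higher.

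Of 23 genes of progenitor and memory-like T cells, 2 were higher, 9 were lower and 12 did not pass (2 and 10 adjusted over the list alone, median log2 difference -0.66, camera adjusted p = 0.0379, adjusted p = 0.593 with an estimated correlation). Klf2 and S1pr1, which control exit from lymphoid tissue, averaged 10.8 ± 0.911 and 12.9 ± 2.64 FPKM in Th1 against 126 ± 43.6 and 117 ± 38.9 FPKM in Th17 cells, and Lef1, a partner of TCF-1, 18.1 ± 5.22 against 73.1 ± 22.3 FPKM. Dapl1 (2.82-fold) and Myb (1.72-fold) were higher in Th1. This list's call was lost without Th1 replicate 2 (adjusted p = 0.196), without Th17-derived Th1 replicate 3 (adjusted p = 0.053) and with libraries rescaled to equal sums (adjusted p = 0.0699). Of 20 genes of inhibitory receptors and exhaustion, 12 were higher, 4 were lower and 4 did not pass (12 and 5 adjusted over the list alone, median log2 difference 1.04, camera adjusted p = 0.00122, adjusted p = 0.452 with an estimated correlation). Havcr2, which encodes TIM-3, averaged 45.3 ± 8.78 against 3.67 ± 1.62 FPKM, 10.2-fold, and Pdcd1, which encodes PD-1, 35.4 ± 4.88 against 9.02 ± 0.1002 FPKM, 3.61-fold. Lag3 (5.52-fold), Nr4a2 (4.37-fold) and Prdm1 (3.88-fold) were also higher, and Cd101 (-3.15), Cd244a (-1.90), Cd200r1 (-0.81) and Vsir (-0.64) were lower by their log2 differences.

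Of 29 interferon-stimulated genes, 16 were higher, 1 was lower and 12 did not pass (16 and 1 adjusted over the list alone, median log2 difference 0.67, camera adjusted p = 3.41e-07, adjusted p = 0.452 with an estimated correlation). Mx1 (10.1-fold), Gbp2 (8.39-fold), Usp18 (6.51-fold) and Gbp5 (4.77-fold) led, and Rtp4 was the member lower in Th1 (log2 difference -1.14). Of 26 genes induced by the T cell receptor, 18 were higher, 0 were lower and 8 did not pass (19 and 0 adjusted over the list alone, median log2 difference 0.97, camera adjusted p = 5.66e-10, adjusted p = 0.38 with an estimated correlation). Nr4a2, Dusp5 (4.24-fold) and Egr2 (3.51-fold) were among them. Of 26 cytokine genes, 12 were higher, 4 were lower and 10 did not pass (12 and 6 adjusted over the list alone, median log2 difference 0.46, camera adjusted p = 0.000526, adjusted p = 0.38 with an estimated correlation). Spp1, which encodes osteopontin, was 23.6-fold higher. The other T cell lists were not called by camera. Fry called the Th17 program (adjusted p = 0.00208), TGF-beta response (0.00283) and chemokine receptor and homing lists (0.000589). It did not call the regulatory T cell (0.0722), Th2 (0.166) or T follicular helper lists (0.192). Of 15 regulatory T cell genes, 6 were higher, 4 were lower and 5 did not pass (6 and 5 adjusted over the list alone, median log2 difference 0.10, camera adjusted p = 0.155, adjusted p = 0.452 with an estimated correlation). Foxp3 averaged 0.729 ± 0.635 against 10.7 ± 2.14 FPKM. Of 16 TGF-beta response genes, 7 were higher, 7 were lower and 2 did not pass (7 and 7 adjusted over the list alone, median log2 difference -0.21, mean -0.33, camera direction up, camera adjusted p = 0.892, adjusted p = 0.908 with an estimated correlation). Of 23 chemokine receptor and homing genes, 7 were higher, 10 were lower and 6 did not pass (7 and 10 adjusted over the list alone, median log2 difference -0.48, camera adjusted p = 0.505, adjusted p = 0.732 with an estimated correlation). Of 11 Th2 program genes, 1 was higher, 4 were lower and 6 did not pass (1 and 4 adjusted over the list alone, median log2 difference -0.28, camera adjusted p = 0.892, adjusted p = 0.908 with an estimated correlation). Of 14 T follicular helper genes, 4 were higher, 3 were lower and 7 did not pass (4 and 3 adjusted over the list alone, median log2 difference 0.19, camera adjusted p = 0.175, adjusted p = 0.732 with an estimated correlation).

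In all, 1478 of 10538 genes were higher and 3048 lower in Th1 than in Th17 cells, 529 and 469 of them by at least 2-fold. The median gene stood at -0.17 log2 units in the deposited values and at -0.02 with median-ratio scaling. The split of calls depended on scaling: 32.7% were higher as deposited, 26.7% with equal sums, 53.8% with median-ratio scaling (2045 higher and 1759 lower) and 45.6% with quantile normalization. With array weights the counts were 2234 and 4882, and replicates 1 and 2 alone gave 1916 lower genes. Without Th17 replicate 1 or 2 the lower genes numbered 1982 or 1938, and of 87 named genes called in this comparison, 76 kept the call in each fit without 1 library that tested them. Apol9b, Il17a and Il17f passed the filter in 6 of those 9 fits. The other 11, lost without at least 1 library, were Ccr2, Ccr4, Cd200r1, Cd68, Eomes, Gzmb, Hmgcs1, Icos, Kit, Ly6g and Myb. Settings other than the omission of 1 library ended the calls of Cd200r1, Eomes, Gzmb, Icos, Kit, Ly6g, Myb and Vsir.

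**Figure D2:**
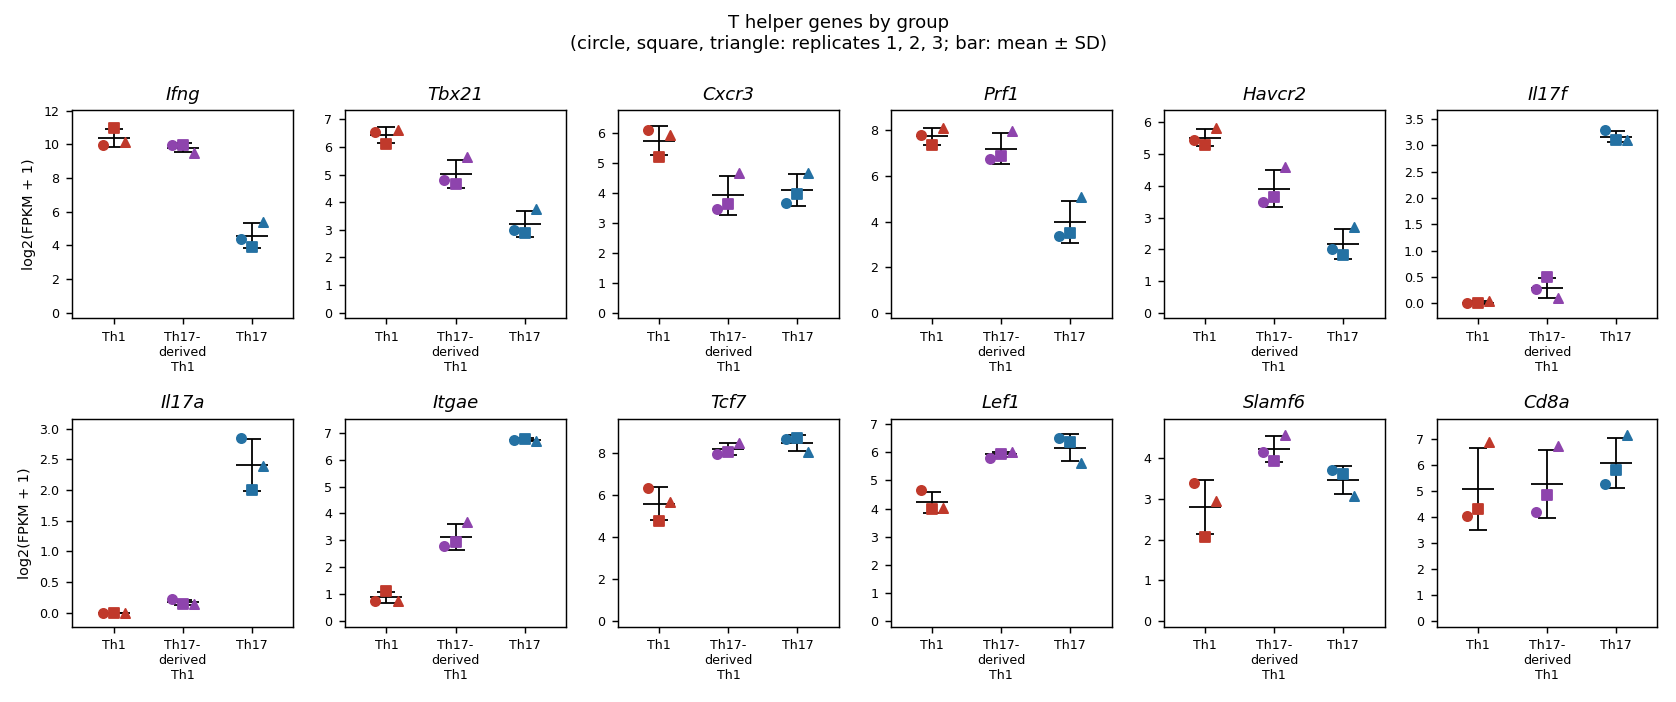
log2(FPKM + 1) of 12 T helper genes in Th1, Th17-derived Th1 and Th17 libraries, each panel with its own axis. Circles, squares and triangles are replicates 1, 2 and 3 with the mean ± SD (n = 3), and in Th17-derived Th1 cells Ifng averages 894 ± 153 and Tcf7 297 ± 60.4 FPKM.

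The second comparison set Th17-derived Th1 against Th17 cells and asked what the switch to the Th1 condition at day 7 went with. RNA of both groups was taken on day 10, and no library holds the state at day 7. Differences are therefore between groups and not changes over time. Ifng averaged 894 ± 153 FPKM in Th17-derived Th1 cells, 37.4-fold above Th17 cells, and Tbx21 averaged 33.0 ± 13.2 FPKM, 3.54-fold. Il17f and Il17a were lower, at 0.235 ± 0.165 and 0.122 ± 0.0333 FPKM (log2 differences -2.87 and -2.24), as was Itgae at 8.10 ± 3.20 FPKM (-3.60). Tcf7 did not pass, at 297 ± 60.4 FPKM (log2 difference -0.31, adjusted p = 0.577). Il21, a cytokine that acts on B cells and on CD8 T cells (chromosome 3, 37222759 to 37232636), averaged 31.0 ± 12.6 against 0.569 ± 0.166 FPKM, 19.5-fold. The limma adjusted p-values of the 6 that passed ran from 1.84e-05 (Il17f) to 0.00436 (Tbx21).

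By size, Ifng and Il21 led the higher genes, followed by P2rx3 (17.6-fold), Gzmd (14.4-fold), Ubd (13.8-fold), Ifi204, an interferon-inducible gene (13.4-fold), Ccl5 (13.2-fold) and Tnfrsf8, which encodes CD30 (12.5-fold). Cdh1, which encodes E-cadherin, led the lower genes at 0.116 ± 0.0380 against 24.2 ± 6.02 FPKM, a log2 difference of -4.47. Ncmap (-3.90), Apol9b (-3.69), Itgae, Gja5 (-3.35), Spsb1 (-3.24), Il17f and Ccr8 (-2.75) followed. The adjusted p-values of these 16 genes ran from 1.84e-05 (Il17f) to 0.00615 (Gzmd).

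Of 29 interferon-stimulated genes, 25 were higher, 0 were lower and 4 did not pass (28 and 0 adjusted over the list alone, median log2 difference 1.09, camera adjusted p = 2.97e-24, adjusted p = 0.154 with an estimated correlation). Gbp2 (11.9-fold), Ifit3 (9.61-fold), Oasl2 (6.56-fold) and Gbp5 (6.37-fold) led. Of 23 Th1 program genes, 10 were higher, 3 were lower and 10 did not pass (11 and 3 adjusted over the list alone, median log2 difference 0.81, camera adjusted p = 1.29e-06, adjusted p = 0.248 with an estimated correlation). Furin was 9.76-fold and Ccl4 6.21-fold higher, Eomes (-1.88), Cd226 (-1.24) and Runx3 (-0.45) were lower by their log2 differences, and the chemokine receptor gene Cxcr3 averaged 15.4 ± 8.05 against 17.1 ± 6.89 FPKM (adjusted p = 0.771). Of 24 cytotoxic effector genes, 6 were higher, 2 were lower and 16 did not pass (6 and 2 adjusted over the list alone, median log2 difference 0.56, camera adjusted p = 0.00133, adjusted p = 0.533 with an estimated correlation). Prf1 averaged 157 ± 80.0 FPKM, 9.28-fold. Gzmb averaged 2663 ± 607 FPKM and did not pass (adjusted p = 0.122). The Cd8a levels and the shift of cytotoxic genes in replicate 3 given above apply to this group too. Of 16 Th17 program genes, 5 were higher, 3 were lower and 8 did not pass (6 and 3 adjusted over the list alone, median log2 difference 0.43, camera adjusted p = 0.00231, adjusted p = 0.238 with an estimated correlation). The 3 lower genes were Il17a, Il17f and Ahr (-1.91), while Il21 and Csf2 (6.02-fold), cytokine genes that other T helper cells also express, Ltb4r1 (5.00-fold) and Batf (2.13-fold) were among the higher genes.

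Of 23 progenitor and memory-like genes, 3 were higher, 4 were lower and 16 did not pass (4 and 5 adjusted over the list alone, median log2 difference 0.03, mean -0.12, camera direction up, camera adjusted p = 0.392, adjusted p = 0.775 with an estimated correlation). Klf2 was lower at 42.7 ± 7.38 FPKM (-1.48), S1pr1 at 51.5 ± 4.61 FPKM (-1.10), and Actn1 (-1.20) and Xcl1 (-2.69) were also lower, while Dapl1 (3.34-fold), Myb (2.14-fold) and Tnfsf8 (1.45-fold) were higher. Of 20 genes of inhibitory receptors and exhaustion, 7 were higher, 4 were lower and 9 did not pass (9 and 4 adjusted over the list alone, median log2 difference 0.24, camera adjusted p = 0.0031, adjusted p = 0.423 with an estimated correlation). Havcr2 averaged 14.9 ± 6.97 FPKM (3.33-fold), Pdcd1 23.5 ± 5.83 (2.41-fold) and Lag3 23.3 ± 14.0 (5.83-fold). Cd244a (-2.59), Cd101 (-1.34) and Cd160 (-1.31) were lower. Tox, a factor of exhausted T cells, averaged 0.863 ± 0.270 against 2.77 ± 0.285 FPKM (-1.02, adjusted p = 0.0427), a call lost in 7 of the 9 fits without 1 library and 5 of 12 other settings (adjusted p 0.0011 to 0.153 over the alternatives).

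Of 14 T follicular helper genes, 7 were higher, 0 were lower and 7 did not pass (8 and 0 adjusted over the list alone, median log2 difference 0.79, camera adjusted p = 2.39e-08, adjusted p = 0.154 with an estimated correlation). P2rx7 (8.59-fold), Il6st (4.79-fold) and Icos (2.26-fold) were higher beside Il21. The member Bcl6 was at 1.33, 1.69 and 5.63 FPKM in Th17-derived Th1 and 3.58, 4.575 and 2.66 in Th17 cells and did not pass. Cxcr5 was too low to test. Of 26 genes induced by the T cell receptor, 9 were higher, 2 were lower and 15 did not pass (11 and 2 adjusted over the list alone, median log2 difference 0.42, camera adjusted p = 5.07e-07, adjusted p = 0.18 with an estimated correlation). Jun (4.46-fold) and Junb (2.19-fold) were among them. Of 26 cytokine genes, 10 were higher, 5 were lower and 11 did not pass (11 and 5 adjusted over the list alone, median log2 difference 0.46, camera adjusted p = 5.4e-05, adjusted p = 0.154 with an estimated correlation). Of 15 regulatory T cell genes, 6 were higher, 2 were lower and 7 did not pass (8 and 3 adjusted over the list alone, median log2 difference 0.74, camera adjusted p = 0.00506, adjusted p = 0.154 with an estimated correlation). Il10, which encodes a suppressive cytokine, averaged 94.6 ± 3.86 against 12.9 ± 5.44 FPKM, 7.21-fold, Il2ra was 4.50-fold higher, and Foxp3 was lower at 2.76 ± 1.46 FPKM (-1.69). Of 11 Th2 program genes, 3 were higher, 1 was lower and 7 did not pass (4 and 1 adjusted over the list alone, median log2 difference 0.37, camera adjusted p = 0.00826, adjusted p = 0.154 with an estimated correlation). Il1rl1 was 7.91-fold and Ecm1 4.35-fold higher. This call was lost without Th17-derived Th1 replicate 1 (adjusted p = 0.072). Camera did not call TGF-beta response genes, of which 5 were higher, 7 were lower and 4 did not pass (5 and 8 adjusted over the list alone, median log2 difference -0.19, camera adjusted p = 0.979, adjusted p = 0.981 with an estimated correlation). Nor did it call the 23 chemokine receptor and homing genes, of which 2 were higher, 7 were lower and 14 did not pass (4 and 7 adjusted over the list alone, median log2 difference -0.10, mean -0.29, camera direction up, camera adjusted p = 0.97, adjusted p = 0.981 with an estimated correlation). Fry called both of these lists (adjusted p = 0.0141 and 0.0142). It did not call the Th17 program (0.116), inhibitory receptor and exhaustion (0.31) or cytotoxic effector lists (0.353), which camera called.

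In all, 678 genes were higher and 1000 lower in Th17-derived Th1 than in Th17 cells, 313 and 182 of them by at least 2-fold. The median gene stood at -0.12 log2 units as deposited and at -0.01 with median-ratio scaling. Here 40.4% of calls were higher as deposited, 37.7% with equal sums, 63.0% with median-ratio scaling (853 higher and 501 lower) and 54.5% with quantile normalization (750 and 625). Array weights gave 1579 and 3024, and replicates 1 and 2 alone gave 522 lower genes. Leaving out Th17-derived Th1 replicate 1 gave 422 and 417 genes, replicate 2 gave 522 lower and replicate 3 gave 604 lower, while leaving out Th17 replicate 1 or 2 gave 382 and 327 or 379 and 302. Of 83 named genes called here, 64 kept the call in each fit without 1 library that tested them, with 6 of 9 such fits for Apol9b, Areg, Il17a, Il17f, Mpeg1 and Serpinb5. The other 19, lost without at least 1 library, were Actn1, Cd101, Cd160, Dusp2, Gzmg, Kit, Lag3, Lax1, Mki67, Msmo1, Mxd4, Myb, Nedd4, Runx3, S1pr1, Sesn2, Tmem158, Tnfsf8 and Tox. Settings other than the omission of 1 library ended the calls of Cd28, Dusp2, Eomes, Foxp3, Gzmg, Kit, Mki67, Nedd4, Runx3, Sema6d, Sesn2 and Tox.

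The third comparison set Th17-derived Th1 against Th1 cells, which shared the Th1 condition from day 7 on and differed in what came before. Tcf7 averaged 297 ± 60.4 against 52.0 ± 26.5 FPKM, 6.08-fold higher in Th17-derived Th1 cells (limma adjusted p = 0.0035), and Lef1 59.8 ± 4.17 against 18.1 ± 5.22 FPKM, 3.26-fold (0.00434). Ccr7, the receptor that guides T cells to lymph nodes, averaged 140.0 ± 11.7 against 30.2 ± 8.37 FPKM, 4.63-fold (adjusted p = 0.00124). Tbx21 and Havcr2 were lower, at log2 differences of -1.40 and -1.61 (adjusted p = 0.0205 and 0.0146). Ifng did not pass, at 894 ± 153 against 1385 ± 548 FPKM (log2 difference -0.58, adjusted p = 0.362). Il17a stood at 0.122 ± 0.0333 FPKM against 0 in Th1 and did not pass (adjusted p = 0.628).

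Ecm1, an extracellular matrix gene, led the higher genes at 185 ± 21.8 against 12.3 ± 5.53 FPKM, 15.0-fold. Il21 (14.0-fold), Gpr15 (10.5-fold), Igfbp4 (8.94-fold), Rtp4 (8.63-fold), Il6ra (7.46-fold), Cyp2s1 (7.42-fold) and Serpinb5 (6.84-fold) followed. 5830411N06Rik (11.3-fold) would stand between Il21 and Gpr15 but was left out of this ranking, as were all predicted or clone names. Csf1 led the lower genes at 18.4 ± 15.0 against 309.6 ± 170.3 FPKM, a log2 difference of -4.05, followed by Irx3 (-3.75), Ccdc136 (-2.90), the granzyme gene Gzmk (-2.61), Esm1 (-2.61), Ppp2r2c (-2.41), Sulf2 (-2.29) and Ly6c2 (-2.18). The adjusted p-values of these 16 genes ran from 4.71e-05 (Irx3) to 0.0488 (Ly6c2).

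Of 23 progenitor and memory-like genes, 12 were higher, 1 was lower and 10 did not pass (13 and 1 adjusted over the list alone, median log2 difference 1.12, camera adjusted p = 6.86e-06, adjusted p = 0.331 with an estimated correlation). Il6ra, Tcf7, Ccr7 and Id3 (4.23-fold) led, and Slamf6, which marks progenitor exhausted cells, averaged 18.02 ± 4.26 against 6.46 ± 3.14 FPKM, 2.68-fold (adjusted p = 0.0253). The Slamf6 call was lost in 4 of the 9 fits without 1 library and 3 of 13 other settings (adjusted p 0.00108 to 0.12 over the alternatives). Xcl1 was the member that was lower (-1.94). Il7r and Bcl6 did not pass (adjusted p = 0.759 and 0.432), at 114 ± 50.6 and 2.89 ± 2.38 FPKM against 103 ± 58.9 and 5.45 ± 3.43 FPKM. Of 20 genes of inhibitory receptors and exhaustion, 4 were higher, 9 were lower and 7 did not pass (4 and 10 adjusted over the list alone, median log2 difference -0.59, camera adjusted p = 0.00585, adjusted p = 0.483 with an estimated correlation). Besides Havcr2, Cd160 (-1.44) and Entpd1 (-1.35) were lower by their log2 differences, and Pdcd1 averaged 23.5 ± 5.83 against 35.4 ± 4.88 FPKM (-0.59, adjusted p = 0.0499). That call was lost in 7 of the 9 fits without 1 library and 7 of 13 other settings (adjusted p 0.000173 to 0.189 over the alternatives). Cd101 (3.52-fold), Btla (2.21-fold), Ctla4 (3.36-fold, adjusted p = 0.0492) and Cd200r1 (1.99-fold, adjusted p = 0.0408) were higher. The Ctla4 call was lost in 7 of the 9 fits without 1 library and 8 of 13 other settings (adjusted p 0.00146 to 0.15) and the Cd200r1 call in 7 of the 9 fits without 1 library and 3 of 13 other settings (adjusted p 0.000153 to 0.15). Lag3 and Tox averaged 23.3 ± 14.0 and 0.863 ± 0.270 FPKM against 23.7 ± 14.1 and 1.40 ± 1.19 FPKM and did not pass (adjusted p = 0.944 and 0.591).

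Of 23 Th1 program genes, 1 was higher, 8 were lower and 14 did not pass (1 and 11 adjusted over the list alone, median log2 difference -0.70, camera adjusted p = 7.49e-08, adjusted p = 0.331 with an estimated correlation). Twist1 (-1.95), Ccl5 (-1.84), Cxcr3 (-1.82) and Fasl (-1.78) were the lowest of the members that passed, Tnf averaged 48.1 ± 6.42 against 82.2 ± 10.7 FPKM (-0.76), and Txk was higher (1.58-fold). Il12rb2, a chain of the IL-12 receptor, averaged 64.9 ± 15.1 against 111 ± 47.1 FPKM (adjusted p = 0.228). Of 24 cytotoxic effector genes, 0 were higher, 5 were lower and 19 did not pass (0 and 10 adjusted over the list alone, median log2 difference -0.74, camera adjusted p = 3.06e-07, adjusted p = 0.449 with an estimated correlation). Gzmk, Klrg1 (-1.99), Fasl and Crtam (-1.26) were the lowest of the members that passed, while Gzmb (-0.40, adjusted p = 0.583) and Prf1 (-0.55, adjusted p = 0.5) did not pass. Replicate 3 of both groups held the most Cd8a and the higher cytotoxic genes described above. Of 16 Th17 program genes, 8 were higher, 0 were lower and 8 did not pass (8 and 2 adjusted over the list alone, median log2 difference 0.58, camera adjusted p = 0.000385, adjusted p = 0.331 with an estimated correlation). Besides Il21, Maf (4.11-fold), Tmem176a (3.83-fold), Tmem176b (3.58-fold) and Ccr6 (3.54-fold) were higher in Th17-derived Th1 cells.

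Of 29 interferon-stimulated genes, 10 were higher, 0 were lower and 19 did not pass (13 and 1 adjusted over the list alone, median log2 difference 0.50, camera adjusted p = 9.56e-05, adjusted p = 0.514 with an estimated correlation). Rtp4 averaged 19.3 ± 1.01 against 1.36 ± 0.305 FPKM, Oasl2 was 5.68-fold, Ifit3 4.59-fold and Irf7, a factor of type I interferon responses, 2.75-fold higher. Of 14 T follicular helper genes, 9 were higher, 1 was lower and 4 did not pass (10 and 2 adjusted over the list alone, median log2 difference 1.03, camera adjusted p = 0.000831, adjusted p = 0.436 with an estimated correlation). Il21, Pou2af1 (5.30-fold), Cd200 (2.80-fold) and Slamf6 stood at the top. The list members Bcl6, which did not pass, and Cxcr5, which was too low to test, were not among the higher genes. Of 11 Th2 program genes, 4 were higher, 1 was lower and 6 did not pass (5 and 1 adjusted over the list alone, median log2 difference 0.85, camera adjusted p = 0.0302, adjusted p = 0.331 with an estimated correlation). Ecm1, Ccr4 (2.72-fold), Il4ra (1.80-fold) and Areg (1.73-fold) were higher and Il1rl1 was lower (-1.59). This call was lost with equal sums (adjusted p = 0.051) and without Th17-derived Th1 replicate 1 or 3 (adjusted p = 0.101 and 0.0761). Of 26 genes induced by the T cell receptor, 0 were higher, 7 were lower and 19 did not pass (1 and 10 adjusted over the list alone, median log2 difference -0.38, camera adjusted p = 0.000168, adjusted p = 0.436 with an estimated correlation). Dusp2 (-1.50), Nr4a2 (-1.24) and Egr3 (-1.22) were among those lower.

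**Figure D3:**
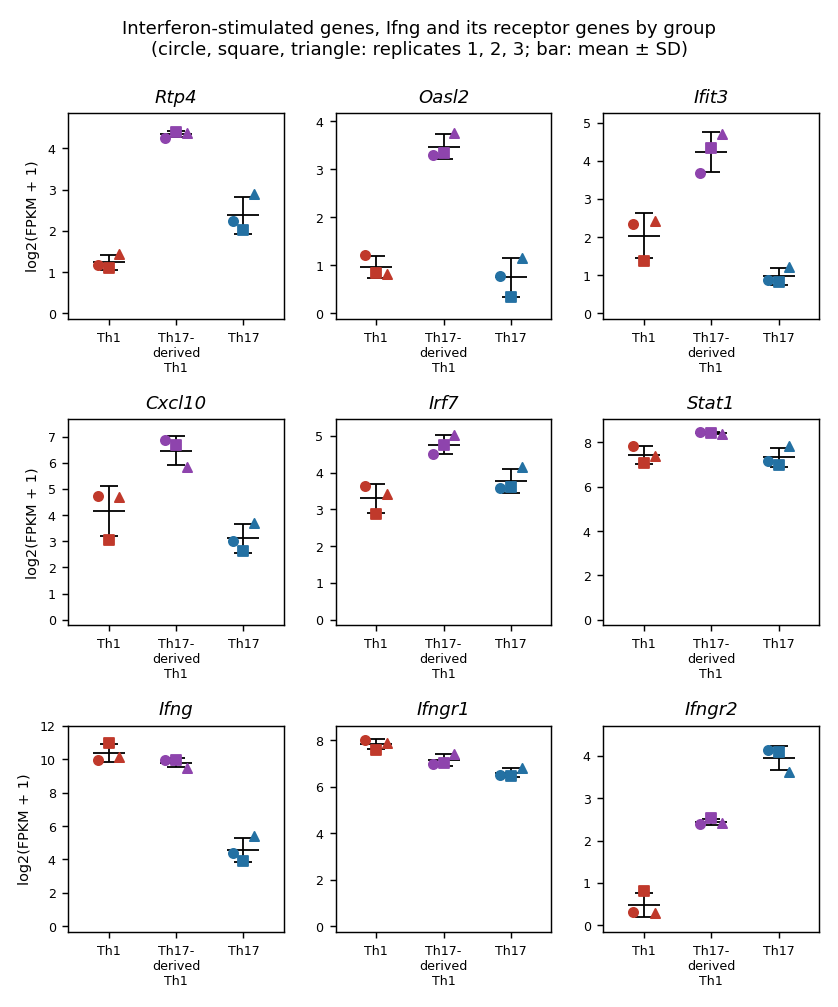
log2(FPKM + 1) of 6 interferon-inducible genes, of Ifng and of the interferon-gamma receptor genes Ifngr1 and Ifngr2 by group, each panel with its own axis. Circles, squares and triangles are replicates 1, 2 and 3 with the mean ± SD (n = 3), and Rtp4 averages 19.3 ± 1.01 FPKM in Th17-derived Th1 against 1.36 ± 0.305 FPKM in Th1 cells.

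Camera called none of the other 4 T cell lists in this comparison. Fry did call the regulatory T cell (adjusted p = 0.00944) and the chemokine receptor and homing lists (0.00408). It did not call TGF-beta response (0.195) or cytokine genes (0.86). Among T cell lists that camera called here, fry did not call cytotoxic effectors (0.108) or inhibitory receptors and exhaustion (0.177). Interferon-stimulated (0.107) and T cell receptor-induced genes (0.052) were not called by fry either. Of 15 regulatory T cell genes, 4 were higher, 0 were lower and 11 did not pass (5 and 1 adjusted over the list alone, median log2 difference 0.49, camera adjusted p = 0.188, adjusted p = 0.436 with an estimated correlation). Foxp3 averaged 2.76 ± 1.46 against 0.729 ± 0.635 FPKM (adjusted p = 0.0504). Of 16 TGF-beta response genes, 2 were higher, 2 were lower and 12 did not pass (4 and 3 adjusted over the list alone, median log2 difference 0.12, camera adjusted p = 0.823, adjusted p = 0.884 with an estimated correlation). Itgae was 4.76-fold and Smad7 1.94-fold higher, the latter (adjusted p = 0.0423) losing its call in 7 of the 9 fits without 1 library and 6 of 13 other settings (adjusted p 0.00321 to 0.146 over the alternatives). Of 23 chemokine receptor and homing genes, 9 were higher, 3 were lower and 11 did not pass (10 and 6 adjusted over the list alone, median log2 difference 0.12, camera adjusted p = 0.155, adjusted p = 0.472 with an estimated correlation). Gpr15, Itgae, Ccr7 and S1pr1 (3.82-fold) led. With quantile normalization this list was called (adjusted p = 0.0476). Of 26 cytokine genes, 2 were higher, 6 were lower and 18 did not pass (3 and 6 adjusted over the list alone, median log2 difference -0.02, camera adjusted p = 0.318, adjusted p = 0.683 with an estimated correlation). Il10 averaged 94.6 ± 3.86 against 93.9 ± 21.7 FPKM (adjusted p = 0.939). Il2, Il23r and Cxcr5 were below the level needed for testing, with means of 0.697, 0.852 and 0.062 FPKM in Th1, 0.428, 1.10 and 0.055 in Th17-derived Th1 and 0.259, 0.228 and 0.429 FPKM in Th17 cells.

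**Figure D4:**
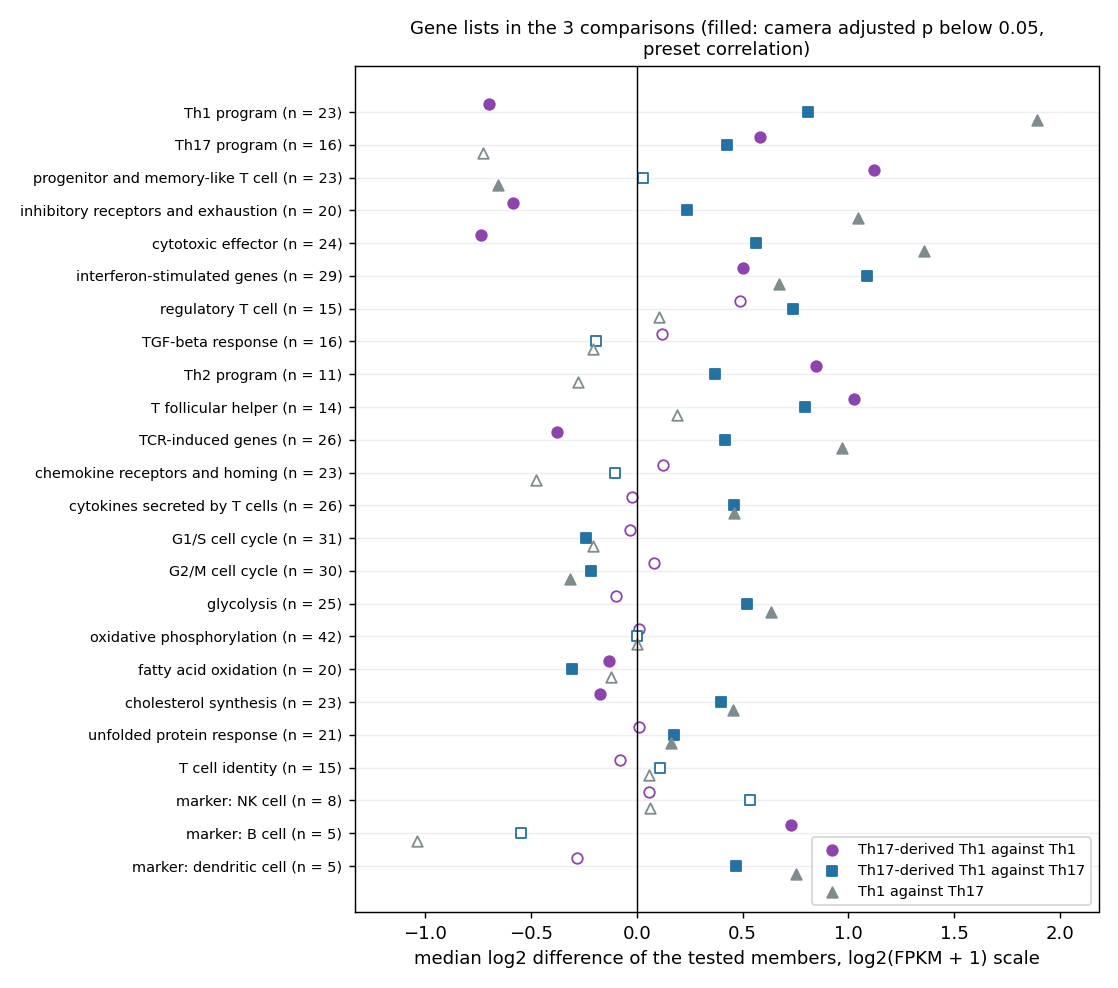
Median log2 difference of the tested members of 24 gene lists in the 3 comparisons, on the log2(FPKM + 1) scale, with filled symbols where camera's adjusted p is below 0.05 at its preset correlation of 0.01. The progenitor and memory-like list lies at 1.12 in Th17-derived Th1 against Th1, 0.03 against Th17 (-0.053 with quantile normalization) and -0.66 in Th1 against Th17.

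In all, 597 genes were higher and 507 lower in Th17-derived Th1 than in Th1 cells, 184 and 143 of them by at least 2-fold. Of the calls, 54.1% were higher as deposited, 61.2% with equal sums, 45.6% with median-ratio scaling (512 and 610) and 45.3% with quantile normalization (504 and 609). Counts of calls were 3419 and 2011 with array weights, 390 and 302 when only these 2 groups were fitted and 290 and 306 with replicates 1 and 2 alone. The counts rested on single libraries more than in the other comparisons: they were 1067 and 794 without Th1 replicate 2 and 240 and 148 without Th1 replicate 3. They were 237 and 151 without Th17-derived Th1 replicate 1 and 195 and 120 without its replicate 2, and without Th1 replicate 1 the lower genes numbered 235. Of 81 named genes called here, 41 kept the call in each fit without 1 library that tested them. Tcf7, Lef1 and Ccr7 were among them, while Irx3, Mpeg1, Serpinb5 and Twist1 passed the filter in 6 of the 9 fits. The other 40 lost it without at least 1 library: Ahr, Apoe, Areg, Ccl5, Ccr4, Cd160, Cd200r1, Cd38, Crtam, Ctla4, Cxcl10, Cxcr3, Dusp5, Egr3, Entpd1, Esm1, Fasl, Gzmk, Havcr2, Il1rl1, Il4ra, Klrg1, Lax1, Ly6c2, Ly6g, Mxd4, Nedd4, Nr4a2, Pdcd1, Sema6d, Serpine2, Sesn2, Slamf6, Smad7, Sorl1, Tbx21, Tmem158, Tnf, Top2a and Txk. Settings other than the omission of 1 library ended the calls of Apoe, Areg, Ccl5, Cd160, Cd200r1, Cd38, Crtam, Ctla4, Egr3, Esm1, Lax1, Ly6c2, Nedd4, Nr4a2, P2rx7, Pcna, Pdcd1, Sema6d, Sesn2, Slamf6, Smad7, Sorl1, Tmem158, Tnf, Top2a, Txk and Xcl1. Regrouping the 6 libraries so that Th1 replicates 1 and 3 stood with Th17-derived Th1 replicate 3 called 2066 genes, more than the 1104 of the real groups.

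The last comparisons placed Th17-derived Th1 cells against both other groups. In 95 genes they were higher than in both, and in 53 lower than in both, where independent lists of these sizes would share 38.4 and 48.1 genes, and simulated groups without effects, sharing the same libraries, gave 0 in 100 simulations. The first value leaves out the shared libraries of Th17-derived Th1 cells and the second leaves out the effects, in which case hardly any gene is called. Neither is a chance value for lists with effects that share libraries, and whether 95 and 53 exceed such a value was not tested. Il21 led the higher genes, at 31.0 ± 12.6 FPKM against 1.21 ± 0.511 in Th1 and 0.569 ± 0.166 in Th17 cells. Serpinb5 (9.68 ± 4.51 FPKM), Oasl2 (10.2 ± 2.08), the chemokine gene Cxcl10 (91.3 ± 31.2), Ifit3 (18.7 ± 6.69), Ly6g (18.2 ± 14.3), Tmem158 (29.7 ± 16.8) and Ecm1 (185 ± 21.8) followed, 3 of them interferon-inducible. Cxcl10 was 4.96-fold above Th1 (adjusted p = 0.0186) and 10.2-fold above Th17 cells (0.0023). Xcl1, a chemokine gene of activated T cells, led the lower genes at 8.26 ± 2.63 FPKM against 36.02 ± 15.1 in Th1 and 57.2 ± 0.707 in Th17 cells. The receptor genes Cd160 (14.6 ± 6.47 FPKM) and Cd226 (14.1 ± 2.77), Mxd4 (9.52 ± 2.66), Lax1 (18.5 ± 7.50), Sema6d (8.96 ± 1.88), Sorl1 (7.94 ± 2.63) and Nedd4 (14.9 ± 5.16) followed. Leaving out 1 library gave 33 to 127 higher and 11 to 82 lower genes, and leaving out the 3 libraries of replicate 3 gave 47 and 42. Array weights gave 403 and 495.

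Over 998 genes that differed at least 2-fold between Th1 and Th17 cells, a position of 0 means the Th17 level and 1 the Th1 level. Th17-derived Th1 cells lay at a median of 0.568 (quartiles 0.365 and 0.804), and their 3 libraries at 0.540, 0.480 and 0.704, a mean of 0.575 ± 0.116 (SD, n = 3). Among the 529 of these genes that were higher in Th1, 234 differed in Th17-derived Th1 cells from Th17 alone, 108 from Th1 alone, 86 from both and 101 from neither, with a median position of 0.614. Among the 469 higher in Th17 cells, the counts were 170, 121, 84 and 94, with a median position of 0.516. Ifng, Prf1 and Il10 belonged to the first kind, with Th17-derived Th1 cells apart from Th17 only, and Tcf7, Lef1 and Ccr7 to the second, apart from Th1 only. Passing against one group and not the other does not show that the 2 differences differ, which was not tested.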

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

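The fits without all replicate 3 libraries and with the mean of Cd8a and Cd8b1 as a covariate were chosen after the results were seen, and all other alternatives before. Over 284 pairs of a named gene and a comparison, 251 of them called, the alternatives gave 6152 values. Of these, 5684 kept their side of the threshold, 417 lost the call and 50 gained it. The 5684 include any value that changed sign while uncalled in both fits, and such changes were not counted. Lag3 in Th17-derived Th1 against Th1, at 0.08 and not called, stood at -0.822 with array weights (adjusted p = 0.0366), and the cause was not tested. Array weights and robust moderation ended 0 of the named calls, testing without the filter 32, fitting only the 2 groups 25, replicates 1 and 2 alone 24, median-ratio scaling 11, quantile normalization 10 and equal sums 2, while leaving out Th17-derived Th1 replicate 1 or 2 ended 53 or 50.

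The median position kept within 0.497 to 0.617 without each library. Counts are given as higher and lower, in the order Th17-derived Th1 against Th1, Th17-derived Th1 against Th17, Th1 against Th17, and Th17-derived Th1 against both. Array weights gave 3419 and 2011, 1579 and 3024, 2234 and 4882, and 403 and 495. At least 2-fold differences gave 184 and 143, 313 and 182, 529 and 469, and 34 and 10. An adjusted p below 0.01 gave 190 and 117, 352 and 316, 905 and 1584, and 34 and 8. Median-ratio scaling left 501 lower genes in Th17-derived Th1 against Th17 and 1759 in Th1 against Th17, and quantile normalization left 625 in the former. Fitting only the 2 groups gave 390 and 302 genes in Th17-derived Th1 against Th1. Replicates 1 and 2 alone gave 290 and 306 in that comparison, 522 lower against Th17, 1916 lower in Th1 against Th17 and 47 higher than both. Of the 596, 1036 and 3067 genes those fits called, 496, 861 and 2879 were also called in the same direction with all libraries. Stricter thresholds lower counts by construction, and the cause of the other shifts was not tested. With an estimated correlation camera called 0, 0 and 0 lists (2, 6 and 3 at an unadjusted p below 0.05).

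Without each library in turn, Th17-derived Th1 against Th1 ranged over 195 to 1067 higher and 120 to 794 lower genes, against Th17 over 379 to 889 and 302 to 1453, and Th1 against Th17 over 1057 to 1662 and 1938 to 3738. Against both, the ranges were 33 to 127 and 11 to 82, and called lists numbered 10 to 14, 15 to 17 and 9 to 12. The count of lower genes in both was 33 without Th1 replicate 1 and 82 without Th1 replicate 2. It was 60 higher and 18 lower without Th1 replicate 3, 34 and 12 or 33 and 11 without Th17-derived Th1 replicate 1 or 2, and 59 and 21 or 59 and 22 without Th17 replicate 1 or 2.

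With the replicate block the counts were 634 and 621, 745 and 936, 1482 and 2970, and 108 and 67, with 12, 17 and 12 lists called. The block ended 5 named calls, of Smad7 (adjusted p = 0.0688) and Txk (0.0703) in Th17-derived Th1 against Th1 and of Runx3 (0.055), Mki67 (0.0581) and Kit (0.0526) against Th17. Same-numbered libraries correlated at -0.178 to 0.659 in their deviations from group means, and 4 of 9 pairs lay over 0.1, so the numbers were not taken to pair the libraries. This rule over all genes cannot exclude a shared source of same-numbered libraries. Gm47283 and Gm21887, described below, followed the number in each group. As a hint from the data, 5 of 9 libraries had a same-numbered library as their single best correlate, and 2 of 9 had it in each of the other groups. The depth of the libraries is unknown, so what depth limits could not be measured.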

Other observations

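The tests of scaling and of replicate 3 for interferon-stimulated genes and all tests on Cd8a, Gm47283 and Gm21887 were chosen only after the results were seen, while the counts of other splits and the interferon-gamma list were set before.

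Of 25 glycolysis genes in Th1 against Th17 cells, 13 were higher, 2 were lower and 10 did not pass (13 and 2 adjusted over the list alone, median log2 difference 0.63, camera adjusted p = 9.63e-06, adjusted p = 0.452 with an estimated correlation). Between Th17-derived Th1 and Th17 cells, 11 were higher, 0 were lower and 14 did not pass (14 and 1 adjusted over the list alone, median log2 difference 0.52, camera adjusted p = 2.39e-08, adjusted p = 0.2 with an estimated correlation). Hif1a, a regulator of glycolysis, averaged 166 ± 35.0 FPKM in Th1, 171 ± 13.1 in Th17-derived Th1 and 54.5 ± 14.1 in Th17 cells, and the lactate exporter gene Slc16a3 was 2.77-fold and 2.41-fold above Th17 cells. In Th17-derived Th1 against Th1, 2 were higher, 0 were lower and 23 did not pass (2 and 0 adjusted over the list alone, median log2 difference -0.10, mean 0.04, camera direction down, camera adjusted p = 0.646, adjusted p = 0.884 with an estimated correlation). The higher genes were Pdk1 (2.98-fold) and Egln3 (2.95-fold). Of 23 cholesterol synthesis genes, 15 were higher, 0 were lower and 8 did not pass (16 and 0 adjusted over the list alone, median log2 difference 0.45, camera adjusted p = 2.33e-07, adjusted p = 0.452 with an estimated correlation) in Th1 against Th17. Msmo1 (2.02-fold) and Hmgcs1 (1.90-fold) led. In Th17-derived Th1 cells, 1 was higher, 0 were lower and 22 did not pass (1 and 0 adjusted over the list alone, median log2 difference 0.40, camera adjusted p = 2.35e-06, adjusted p = 0.405 with an estimated correlation) against Th17. Set against Th1 cells, 0 were higher, 0 were lower and 23 did not pass (0 and 0 adjusted over the list alone, median log2 difference -0.17, camera adjusted p = 0.00875, adjusted p = 0.683 with an estimated correlation). The last call was lost without Th1 replicate 3 (adjusted p = 0.0574) or Th17-derived Th1 replicate 2 (0.0797). Of the cholesterol synthesis calls, fry made that in Th1 against Th17 (adjusted p = 0.0368). It made neither that in Th17-derived Th1 against Th17 (0.146) nor that against Th1 (0.537). Both glycolysis calls above Th17 cells were made by fry (0.0286 and 0.0145).

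Of 20 fatty acid oxidation genes, 0 were higher, 4 were lower and 16 did not pass (1 and 6 adjusted over the list alone, median log2 difference -0.13, camera adjusted p = 0.0117, adjusted p = 0.331 with an estimated correlation) in Th17-derived Th1 against Th1. Compared with Th17, 1 was higher, 5 were lower and 14 did not pass (1 and 9 adjusted over the list alone, median log2 difference -0.31, camera adjusted p = 0.0347, adjusted p = 0.18 with an estimated correlation). Cpt1a, which carries fatty acids toward oxidation, was at a log2 difference of -0.96. The first call was lost without Th1 replicate 2 (adjusted p = 0.0591) and the second without Th17-derived Th1 replicate 2 (0.0623). In Th1 against Th17, 4 were higher, 9 were lower and 7 did not pass (4 and 9 adjusted over the list alone, median log2 difference -0.12, mean -0.10, camera direction up, camera adjusted p = 0.892, adjusted p = 0.908 with an estimated correlation). Of 42 oxidative phosphorylation genes, 0 were higher, 3 were lower and 39 did not pass (0 and 2 adjusted over the list alone, median log2 difference 0.01, mean -0.00, camera direction down, camera adjusted p = 0.33, adjusted p = 0.881 with an estimated correlation) in Th17-derived Th1 against Th1. Against Th17, 0 were higher, 1 was lower and 41 did not pass (0 and 0 adjusted over the list alone, median log2 difference 0.00, mean -0.01, camera direction up, camera adjusted p = 0.239, adjusted p = 0.807 with an estimated correlation). Between Th1 and Th17, 5 were higher, 5 were lower and 32 did not pass (3 and 1 adjusted over the list alone, median log2 difference 0.00, mean -0.01, camera direction up, camera adjusted p = 0.161, adjusted p = 0.856 with an estimated correlation). With median-ratio scaling the last 2 were called (adjusted p = 0.0494 and 0.0437). Of 21 unfolded protein response genes, 5 were higher, 1 was lower and 15 did not pass (3 and 0 adjusted over the list alone, median log2 difference 0.16, camera adjusted p = 0.00492, adjusted p = 0.593 with an estimated correlation) in Th1 against Th17. This call was lost without Th1 replicate 2 (adjusted p = 0.115, median -0.01) and with quantile normalization (0.053). In Th17-derived Th1 against Th17, 3 were higher, 0 were lower and 18 did not pass (3 and 0 adjusted over the list alone, median log2 difference 0.18, camera adjusted p = 0.00111, adjusted p = 0.434 with an estimated correlation). Against Th1, 0 were higher, 1 was lower and 20 did not pass (0 and 1 adjusted over the list alone, median log2 difference 0.01, mean -0.02, camera direction down, camera adjusted p = 0.348, adjusted p = 0.881 with an estimated correlation). Sesn2, a stress gene, was 2.34-fold higher in Th1 than in Th17 cells. Neither unfolded protein response call was made by fry (adjusted p = 0.16 and 0.249), whereas both fatty acid oxidation calls were (0.00648 and 0.00222).

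Of 30 G2/M genes, 0 were higher, 13 were lower and 17 did not pass (0 and 13 adjusted over the list alone, median log2 difference -0.32, camera adjusted p = 0.0165, adjusted p = 0.732 with an estimated correlation) in Th1 against Th17. With Th17-derived Th1 against Th17, 0 were higher, 3 were lower and 27 did not pass (0 and 2 adjusted over the list alone, median log2 difference -0.22, camera adjusted p = 0.0274, adjusted p = 0.743 with an estimated correlation). The proliferation marker gene Mki67 was at a log2 difference of -0.35 there. Beside Th1, 1 was higher, 0 were lower and 29 did not pass (0 and 0 adjusted over the list alone, median log2 difference 0.08, camera adjusted p = 0.188, adjusted p = 0.881 with an estimated correlation), Top2a being higher (1.49-fold). Both G2/M calls were lost with median-ratio scaling (adjusted p = 0.0545 and 0.0702) and without Th17 replicate 3 (0.105 and 0.262). The first was also lost without Th1 replicate 2 or 3 (0.0899 and 0.0591) and the second without Th17-derived Th1 replicate 3 (0.23). Of 31 G1/S genes, 1 was higher, 4 were lower and 26 did not pass (1 and 1 adjusted over the list alone, median log2 difference -0.21, camera adjusted p = 0.505, adjusted p = 0.908 with an estimated correlation) in Th1 against Th17. Between Th17-derived Th1 and Th17, 0 were higher, 1 was lower and 30 did not pass (0 and 0 adjusted over the list alone, median log2 difference -0.24, camera adjusted p = 0.0406, adjusted p = 0.77 with an estimated correlation). Between Th17-derived Th1 and Th1, 0 were higher, 1 was lower and 30 did not pass (0 and 1 adjusted over the list alone, median log2 difference -0.03, camera adjusted p = 0.26, adjusted p = 0.881 with an estimated correlation). The G1/S call was lost without Th1 replicate 1 (0.0585), Th17-derived Th1 replicate 3 (0.669) or Th17 replicate 3 (0.304). Of the cell cycle calls, fry made that of G2/M genes in Th1 against Th17 (adjusted p = 0.0368). It did not call G2/M or G1/S genes in Th17-derived Th1 against Th17 (0.146 and 0.245). Pcna, a replication clamp gene, was higher in Th1 than in Th17 cells (1.66-fold).

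Of 15 T cell identity genes, 4 were higher, 2 were lower and 9 did not pass (4 and 2 adjusted over the list alone, median log2 difference 0.06, camera adjusted p = 0.174, adjusted p = 0.593 with an estimated correlation) in Th1 against Th17. For Th17-derived Th1 against Th17, 2 were higher, 2 were lower and 11 did not pass (2 and 3 adjusted over the list alone, median log2 difference 0.11, camera adjusted p = 0.147, adjusted p = 0.503 with an estimated correlation). For Th17-derived Th1 against Th1, 1 was higher, 0 were lower and 14 did not pass (1 and 0 adjusted over the list alone, median log2 difference -0.08, mean 0.00, camera direction down, camera adjusted p = 0.348, adjusted p = 0.715 with an estimated correlation). The costimulatory receptor gene Cd28 averaged 121 ± 35.4, 114 ± 4.86 and 48.6 ± 5.86 FPKM in Th1, Th17-derived Th1 and Th17 cells. Of 8 NK cell markers, 1 was higher, 2 were lower and 5 did not pass (2 and 2 adjusted over the list alone, median log2 difference 0.06, mean -0.12, camera direction up, camera adjusted p = 0.575, adjusted p = 0.82 with an estimated correlation) in Th1 against Th17. As Th17-derived Th1 was set against Th17, 1 was higher, 2 were lower and 5 did not pass (3 and 2 adjusted over the list alone, median log2 difference 0.53, mean -0.00, camera direction up, camera adjusted p = 0.244, adjusted p = 0.533 with an estimated correlation). As it was set against Th1, 0 were higher, 0 were lower and 8 did not pass (0 and 0 adjusted over the list alone, median log2 difference 0.06, camera adjusted p = 0.886, adjusted p = 0.918 with an estimated correlation). Of 5 B cell markers, 0 were higher, 4 were lower and 1 did not pass (0 and 4 adjusted over the list alone, median log2 difference -1.04, camera adjusted p = 0.14, adjusted p = 0.597 with an estimated correlation) in Th1 against Th17. From Th17 to Th17-derived Th1, 1 was higher, 3 were lower and 1 did not pass (1 and 3 adjusted over the list alone, median log2 difference -0.55, camera adjusted p = 0.364, adjusted p = 0.743 with an estimated correlation). From Th1 to Th17-derived Th1, 2 were higher, 0 were lower and 3 did not pass (4 and 0 adjusted over the list alone, median log2 difference 0.73, camera adjusted p = 0.0403, adjusted p = 0.483 with an estimated correlation). The last call was lost with equal sums (adjusted p = 0.062), quantile normalization (0.0605) and without Th1 replicate 2 (0.257) or Th17-derived Th1 replicate 1 or 3 (0.059 and 0.177). That call was not made by fry (adjusted p = 0.0501), which did call B cell markers in Th1 against Th17 (0.00374). Of 5 dendritic cell markers, 3 were higher, 0 were lower and 2 did not pass (3 and 0 adjusted over the list alone, median log2 difference 0.75, camera adjusted p = 0.0278, adjusted p = 0.452 with an estimated correlation) in Th1 against Th17. For Th17-derived Th1 relative to Th17, 1 was higher, 0 were lower and 4 did not pass (1 and 1 adjusted over the list alone, median log2 difference 0.47, camera adjusted p = 0.0274, adjusted p = 0.253 with an estimated correlation). Relative to Th1, 0 were higher, 1 was lower and 4 did not pass (1 and 2 adjusted over the list alone, median log2 difference -0.28, camera adjusted p = 0.348, adjusted p = 0.683 with an estimated correlation). Batf3, a factor that T cells also express, led at 6.59-fold and 7.45-fold above Th17 cells. Dendritic cell markers had medians above 0 in replicate 3 of each group (0.323, 0.456 and 0.577), as given for NK and B cell markers. The dendritic cell calls were lost with median-ratio scaling (0.072 and 0.0702) and quantile normalization (0.053 and 0.0664).

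Markers of other cell types were too few for a list test. Of CD8 markers 2 were tested, of macrophage markers 4 (Apoe, Mpeg1, Cd68 and Ccr2), of gamma-delta, neutrophil and mast cell markers 1 each (5830411N06Rik, Ly6g and Kit) and of erythroid markers 0. In Th17-derived Th1 against Th1 cells, 5830411N06Rik was 11.3-fold, Mpeg1 2.93-fold, Apoe 1.81-fold and Ly6g 4.55-fold higher, while Cd68, Ccr2 and Kit did not pass (adjusted p = 0.421, 0.188 and 0.741). Those that passed against Th17 cells had log2 differences in Th17-derived Th1 of 1.71 for 5830411N06Rik, 3.51 for Ly6g, 1.13 for Mpeg1 and 0.78 for Kit. In Th1 against Th17 cells they were -1.79 for 5830411N06Rik, 1.32 for Ly6g, 0.66 for Kit, 1.79 for Ccr2, 1.42 for Cd68 and -1.45 for Apoe. Cd8a and Cd8b1 passed in none of the 3 comparisons (limma's adjusted p = 0.376 to 0.919), a test that counts the replicate 3 levels as spread. In replicates 1, 2 and 3, Cd8a was at 15.3, 19.0 and 117 FPKM in Th1 and 17.4, 27.4 and 104 in Th17-derived Th1. In Th17 cells it was at 37.4, 54.9 and 141, the highest of the groups for each number, and Cd8b1 was also highest there. A difference between groups in CD8 transcripts is therefore not excluded. Gapdh, chosen after its values were seen, was at 14.3 to 70.7 FPKM, below Pgk1 of the same pathway at 195 to 482 FPKM.

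Of 29 interferon-stimulated genes, 10 were higher in Th17-derived Th1 than in Th1 cells and 19 did not pass (camera adjusted p = 9.56e-05, adjusted p = 0.514 with an estimated correlation). Fry did not call this list (adjusted p over the tested lists = 0.107). Mx1 and Usp18 stood at -1.73 and -0.84, and Ifng did not pass. The tables argue against scaling and against the libraries of replicate 3 as the whole cause: the list's median log2 difference was 0.448 with median-ratio scaling and 0.536 with replicates 1 and 2 alone. A candidate explanation from the culture history is interferon-gamma acting through a receptor chain that Th1 cells carry less of, Ifngr2 (chromosome 16, 91547072 to 91565623), which averaged 0.409 ± 0.296 FPKM in Th1, 4.45 ± 0.281 in Th17-derived Th1 and 14.7 ± 2.93 in Th17 cells, although the other chain, Ifngr1, ran the opposite way at 229.5 ± 33.6, 142 ± 25.7 and 96.8 ± 13.2 FPKM. A list weighted to interferon-gamma had a median log2 difference of 0.31 (limma's fry, adjusted p over 6 tests = 0.414), and a list weighted to type I interferon had 0.823 (adjusted p = 0.005). With 2 of 19 and 8 of 17 genes higher and the difference between the lists not tested, the explanation stays open, and Ifnb1 was listed at 0 in all 9 libraries.

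Cd8a and Cd8b1 were highest in replicate 3 of each group, by 2.71 and 2.96 log2 units over replicates 1 and 2 in Th1, 2.20 and 2.09 in Th17-derived Th1 and 1.61 and 1.75 in Th17 cells. The tables argue against a general shift of T cell transcripts, since 14 identity genes other than Cd4 moved by a median of 0.05, 0.09 and -0.07 (-0.069 in Th17, where the share of the Cd8a change was largest). More CD8 T cells in place of CD4 T cells may account for it: Cd4 was lower in Th1 and Th17 (-0.80 and -0.80) but not in Th17-derived Th1 (0.12), a mean of -0.491, so this stays open. NK cell markers were also higher in replicate 3, by medians of 0.595, 0.463 and 0.447, and no explanation from the design was tested, since it names no condition that differs between replicates. With the mean log2(FPKM + 1) of Cd8a and Cd8b1 as a covariate the counts were 719 higher and 659 lower in Th17-derived Th1 against Th1. They were 776 and 1114 against Th17 and 1522 and 3162 in Th1 against Th17.

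Gm47283 (chromosome Y, 90784738 to 90816464) and Gm21887 (chromosome X, 170009659 to 170019281) followed the replicate number in each group. Both lie near the boundary of the pseudoautosomal region, which the X and Y chromosomes share, so their levels do not tell the sex of the animals. Gm47283 was at 0 in replicate 1, 19.2 to 23.0 FPKM in replicate 2 and 67.4 to 120.5 in replicate 3, and Gm21887 at 0 to 0.0289, 22.8 to 28.1 and 45.9 to 124.5 FPKM. It may be that same-numbered libraries share an animal, pool or batch: with these genes left out, 4 others passed limma's test of the replicate number (Klrc2, Cd8b1, Cd8a and Gm6020). Of 36 relabellings within groups, 1 gave as many, the real labels themselves, and the highest of the others gave 0. The deviations over all genes did not meet the requirement for pairing, and no biological explanation was tested.

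Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Th17-derived Th1 against Th1 called 1104 genes, with 2066 as the highest of the other splits, and 2 of 10 splits gave as many. Th17-derived Th1 against Th17 called 1678, the highest other 1, and Th1 against Th17 called 4526, the highest other 0, each with 1 split as large. Lists called were 12 against 14, 17 against 14 and 12 against 12, with 2, 1 and 2 splits as large. For genes set apart from both other groups, 3 of 100 splits of 9 libraries gave as many as the 95 higher and 3 as many as the 53 lower, the real one included. Splits that mix groups with real differences widen the spread and tend to call few genes, so this share alone does not exclude chance, and the lower genes numbered 11 without Th17-derived Th1 replicate 2. The highest other splits gave 430 and 1188 genes, several times the real counts, and set Th1 replicates 1 and 3 and Th17-derived Th1 replicate 3 apart, which points to a structure of the samples beyond the groups.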
